A study of Homo sapiens with 6 samples.

How the data were processed

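Messenger RNA of Huh7 cells, an established human hepatocellular carcinoma line, was sequenced at day 2 in 2 groups of 3 libraries, transfected with mimics-NC (a negative control mimic) or with miR-361-3p mimics (synthetic microRNA). Per the labels, the mimics came from RiboBio, transfection used a lipid reagent, RNA was taken up in TRIzol and libraries were made with a stranded mRNA kit for the MGI platform. The sequences of the mimic and of the negative control are not given in the sources used here; the mimic was taken to have the sequence of mature miR-361-3p, which was not checked. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these libraries. The miR-361-3p mimics library of replicate 3 carries Huh8 in its cell line tag, while its title says Huh7, and it was kept with its group. The mimics-NC libraries carry a treatment tag that names wild type Huh7 cells, while their titles and the protocol name mimics-NC, and whether the tag is a slip is not known.

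The authors deposited 1 table of RPKM (reads per kilobase of gene length and per 1000000 assigned reads) for 33707 genes in all 6 libraries. In that table the authors also gave each gene's length in bases, a unit of another kind, and its position on GRCh38. Per the submitters' processing notes, the tools were Trimmomatic 0.36, featureCounts of Subread 1.5.1 and edgeR 3.12.1. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands may be shared. RPKM times length in kilobases summed to 1000000 in every library, so no scaling between libraries was present beyond the total. The whole read numbers behind the values were recovered from these products, with 100% of values within 0.01 of a whole number.

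The recovered totals were 42196419, 52977132 and 47616126 assigned reads in the mimics-NC libraries and 35020139, 44774192 and 44710704 in the mimic libraries. At these depths a gene of 2 kilobases with an RPKM of 1 rests on 70.0 to 106 reads per library. Replicate libraries varied more than counting error allows, with a chi-square per degree of freedom of 5.02 to 12.4 for pairs within a group.

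Genes with a mean of at least 1 RPKM over the 6 libraries were tested, which left 13158 genes. Values were taken as log2(RPKM + 0.5) and fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 are said to rise or fall. The added 0.5 draws fold changes toward 0, most of all for genes near 1 RPKM. The genes named in the text were fixed by rule before the data were examined: the 12 genes with the highest and the 12 with the lowest log2 fold change among those past the threshold with no overlap between groups (genes with a clone name, such as RP11-429J17.5, or a name that is no symbol in the references used, such as RFPL3-AS1_2, are counted but not named by the rule), up to 4 members of each gene list past the threshold (or the most abundant members, to make 2), the microRNA's host gene CHM, and the 8 genes with the largest fall that hold an 8mer site. Genes named outside this rule are said to be chosen after their values were seen. MIR361, the precursor, was not analysed here.

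A set of 34 gene lists with 599 entries was written before the data were examined, and 592 entries were found, 23 of them under an older symbol at the same position. The matching of older symbols by position was corrected after results had been seen. The lists cover microRNA machinery, hepatocyte secreted proteins, hepatocyte transcription factors, drug and bile acid metabolism, the acute phase response, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation, glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, p53 targets, apoptosis, the unfolded protein response, the amino acid and ATF4 response, the interferon response, NF-kB and inflammation, hypoxia, the NRF2 response, metallothioneins, heat shock, Wnt targets, TGF-beta and epithelial-mesenchymal transition, MYC targets and ribosome biogenesis, ribosomal proteins, autophagy and lysosome, MAPK feedback, and markers of immune, endothelial, fibroblast or stellate, and cholangiocyte cells. The 27 lists with at least 5 members tested were compared with all other genes by camera of limma, with the preset correlation of 0.01 between genes, and adjusted over the 27 lists. The same test was repeated with an estimated correlation, and fry of limma tested each list by itself.

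Sites of miR-361-3p were derived from its sequence, UCCCCCAGGUGUGAUUCUGAUUU, as the complement of bases 2 to 8 (7mer-m8, CTGGGGG), of bases 2 to 7 followed by A (7mer-A1, TGGGGGA) and of both (8mer, CTGGGGGA). They were searched in the longest 3' UTR of each protein-coding gene in GENCODE release 29, which has no tag for a canonical transcript, so the longest 3' UTR was used throughout. Of the genes in the table, 33050 were matched to GENCODE: 23166 by name, 475 by synonym and 9409 by identical bounds. The matching by synonym and by bounds was added after first results had been seen. Of the 10108 protein-coding genes tested, 97.4% had a 3' UTR. Genes with a site were compared with genes without by camera, and the difference of medians was set against that of all 42 7-mers with the bases of the 7mer-m8 site. Sites of miR-361-5p, miR-122-5p and miR-1-3p served as controls.

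The alternatives comprised pseudocounts of 0.1 and 1, no filter, minimums of 0.5 and 5 RPKM, median-of-ratios, quantile and TPM scaling, limma without the trend, with robust moderation or with array weights, a replicate block, leaving out each library in turn, a minimum absolute log2 fold change of 1, an adjusted p under 0.01, protein-coding genes alone, and other definitions of a site. Limma's voom on the recovered reads, scaling without the mitochondrially encoded genes and 3' UTRs of principal transcripts (APPRIS) were chosen after seeing the data. The procedure was tested on simulated data drawn with the mean of each gene and the spread of genes of like abundance, with 200 genes changed. It recovered 32% of genes changed 1.25-fold, 64% of those changed 1.5-fold and 92% of those changed 2-fold, with 3 false calls, and made 0 calls by limma over 13139 genes when none was changed. The data gave 2835 calls, so the Benjamini-Hochberg cut differed, and these shares do not give the recovery in the data. In a test on the measured values, lowering every gene with a site by 5% gave a camera p of 9.8e-05, and lowering them by 2% gave 0.105. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.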

Results

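Transcript levels were measured in Huh7 cells, a line from a human hepatocellular carcinoma, at day 2 with either mimics-NC or miR-361-3p mimics, 3 libraries each. The libraries held 35020139 to 52977132 assigned reads. Mitochondrially encoded genes took 5.95% to 6.32% of the assigned reads in the mimics-NC libraries and 5.57% to 6.79% in the mimic libraries. Across the 13158 genes tested, which are not independent replicates, log2 values correlated with Pearson's r of 0.9927 to 0.9947 between libraries of a group and 0.9870 to 0.9896 between libraries of different groups. The first principal component held 46.5% of the variance. The median coefficient of variation of a gene was 5.22% among the mimics-NC libraries and 5.30% among the mimic libraries.

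The first comparison asked which transcripts differed between cells with the mimic and cells with the control. SOAT1, which esterifies cholesterol (chromosome 1, 179293714 to 179358680, GRCh38), fell from 14.6 ± 0.629 to 4.97 ± 0.329 RPKM (mean ± SD, n = 3), a log2 fold change of -1.46. MYBL2, a transcription factor of proliferating cells (chromosome 20, 43667019 to 43716496), fell from 132 ± 1.86 to 51.9 ± 2.30 RPKM, a log2 fold change of -1.34. CCNE1, cyclin E1 of the entry into S phase (chromosome 19, 29811898 to 29824308), fell from 10.0 ± 0.211 to 4.76 ± 0.227 RPKM. EREG, epiregulin, a ligand of the EGF receptor (chromosome 4, 74365143 to 74388751), rose from 3.90 ± 0.0863 to 9.39 ± 0.390 RPKM, a log2 fold change of 1.17. TPM4, a tropomyosin of the actin cytoskeleton (chromosome 19, 16067021 to 16103005), rose from 77.2 ± 2.86 to 151 ± 6.05 RPKM.

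In all, 1539 genes rose and 1296 fell, 2835 of the 13158 tested, and 4721 had an unadjusted p under 0.05. Under median-of-ratios scaling more genes fell than rose, 1453 against 1356, so which direction held more genes depends on the scaling. Most changes were small: the median absolute log2 fold change of the genes past the threshold was 0.28, and only 79 rose and 111 fell by at least 1.5-fold. On the log2(RPKM + 0.5) scale, 2 genes rose at least 2-fold, EREG and the antisense transcript RP11-429J17.5 (1.06). On that scale 5 genes fell as far, SOAT1, MYBL2, CCNE1, C2orf48 and RFPL3-AS1_2 (-1.32, on a mean of 4.0 reads). The added 0.5 draws these folds toward 0. By RPKM means, other genes also changed more than 2-fold. Among them ANKRD1 (3.51 to 7.46) and CXCL1 (3.47 to 7.16) rose, and ABCB10 (4.17 to 1.92), ZMYND19 (13.8 to 6.47) and SH3GL1 (12.6 to 6.25) fell. RP11-429J17.5 and RFPL3-AS1_2 were named after their values were seen, and the call of RFPL3-AS1_2 held only without mimics-NC replicate 2 or mimic replicate 1 (adjusted p up to 0.0746). For all 2835 genes the 3 values of one group lay apart from the 3 of the other, which a call at this threshold favours. The same held for 41.4% of all genes tested, against 10% by chance for a single gene. All genes share the same 6 libraries, so setting these shares side by side does not measure a departure from chance. Among protein-coding genes, 1260 rose and 1119 fell of 10108 tested. With 1 library fewer the count lay between 1780 and 2150 genes, with 1780 without mimics-NC replicate 2, 1859 without mimics-NC replicate 3 and 1820 without mimic replicate 3. The number of genes that rose was 995 without mimic replicate 1, and 895, 958 and 931 without those 3 libraries, in that order.

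The other genes with the largest falls had varied roles. SH3GL1, an endophilin of endocytosis (chromosome 19, 4360370 to 4400547), fell from 12.6 ± 0.534 to 6.25 ± 0.124 RPKM. NUF2, a kinetochore protein (chromosome 1, 163266576 to 163355764), fell from 20.6 ± 1.62 to 10.6 ± 0.306 RPKM. ABCB10, a mitochondrial transporter (chromosome 1, 229516582 to 229558695), fell from 4.17 ± 0.278 to 1.92 ± 0.1001 RPKM. PHF8, a histone demethylase (chromosome X, 53936676 to 54048958), fell from 4.02 ± 0.130 to 2.01 ± 0.0940 RPKM. NELFCD, a subunit of the negative elongation factor (chromosome 20, 58981208 to 58995133), had a log2 fold change of -0.83, and UBE2M, a NEDD8-conjugating enzyme (chromosome 19, 58555712 to 58558960), one of -0.83. The long noncoding RNA C2orf48 (-1.07), ZMYND19 (-0.99) and the processed pseudogene ST13P13 (-0.90) fell as well. These 12 genes named for their falls, SOAT1, MYBL2 and CCNE1 included, kept their call with any 1 library left out, and SH3GL1, ABCB10 and NUF2 overlap an annotated gene on the opposite strand.

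Among the largest increases, ANKRD1, a cardiac ankyrin repeat protein (chromosome 10, 90912096 to 90921276), rose from 3.51 ± 0.456 to 7.46 ± 0.594 RPKM. CXCL1, a chemokine for neutrophils (chromosome 4, 73869393 to 73871242), rose from 3.47 ± 0.0716 to 7.16 ± 0.0717 RPKM. The processed pseudogene IGBP1P4 (0.89), the antisense transcript SYNE1-AS1 (0.95, opposite SYNE1) and the microRNA gene MIR6781 (0.98, within BECN1) rose on the log2 scale. MIR6505 within PFKM (0.96), SNORD116-1 within SNHG14 (0.92), MIR3184 (0.89) and the RNA gene RNU1-59P (0.88) passed the threshold on a mean of 14.2, 6.67, 5.67 and 8.0 reads. Whether the reads of the short genes come from the transcripts around them was not tested. TPM4 lies opposite the gene CTD-2231E14.2 and holds 1 TCGGAGA in its 3' UTR, while EREG, ANKRD1, CXCL1 and LYRM5 hold 0. Genes with this 7-mer, TPM4 included, lay 0.086 above genes without it on the log2 scale, corrected for 3' UTR length, GC content and expression. The 7-mer was picked by a scan of these same fold changes, and whether it bears on the rise of TPM4 was not tested. The call of MIR6505 held only without mimics-NC replicate 1 or 2, that of SNORD116-1 only without mimics-NC replicate 1 or mimic replicate 2, that of MIR3184 only without mimics-NC replicate 2 or 3 or mimic replicate 1, and that of RNU1-59P only without mimics-NC replicate 1 or mimic replicate 1 or 3, with adjusted p up to 0.103, 0.0754, 0.110 and 0.0585 in the remaining fits.

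**Figure D1:**
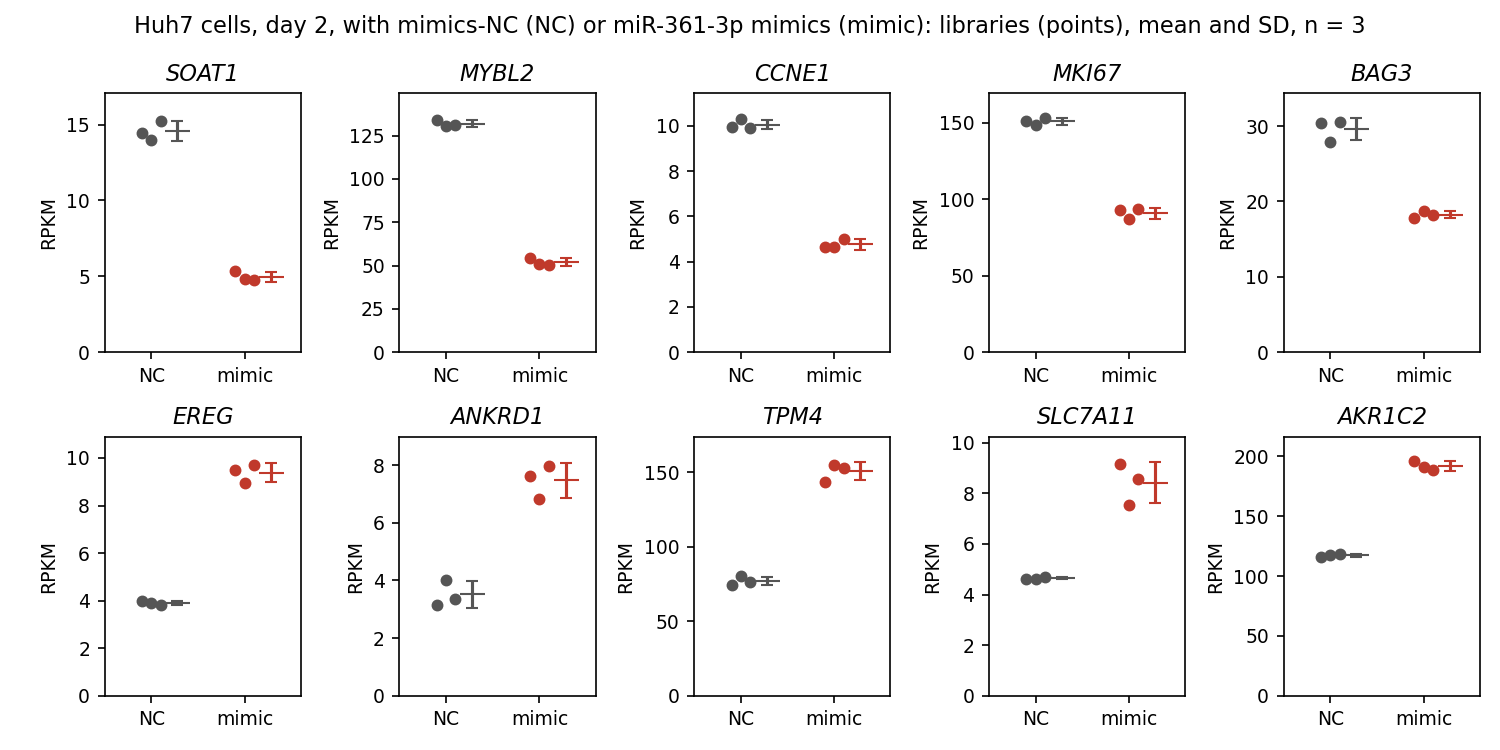
RPKM (vertical axes, linear from 0) of 10 genes in the 3 mimics-NC libraries (NC) and the 3 miR-361-3p mimics libraries (mimic). Points are libraries, and the bars beside them give the mean and SD. For each gene the libraries of one group lie apart from those of the other, as for SOAT1 (14.6 against 4.97 RPKM) and EREG (3.90 against 9.39 RPKM).

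The gene lists written before the data were examined asked which known groups of genes moved together. All 26 genes of the G2/M and mitosis list fell (26 adjusted over the list alone), with a median log2 fold change of -0.54. The proliferation marker MKI67 fell from 151 ± 2.35 to 90.9 ± 3.63 RPKM. The mitotic kinesin KIF20A fell from 18.3 ± 0.544 to 10.3 ± 0.232 RPKM, the DNA topoisomerase TOP2A from 64.0 ± 1.28 to 40.4 ± 0.887 RPKM, and FOXM1, a transcription factor of mitotic genes, from 9.12 ± 0.432 to 5.61 ± 0.245 RPKM. In the G1/S and DNA replication list 20 of 26 genes fell and 0 rose by limma (23 fell adjusted over the list alone), with a median of -0.32. Besides CCNE1, the epigenetic regulator UHRF1 fell from 19.7 ± 0.681 to 12.02 ± 0.0861 RPKM, the thymidylate synthase TYMS from 72.7 ± 0.304 to 47.1 ± 2.17 RPKM, and GINS1, of the replicative helicase, from 6.54 ± 0.290 to 4.37 ± 0.469 RPKM. Camera gave an adjusted p of 6.8e-24 for the G2/M list (adjusted p = 0.056 with an estimated correlation) and 1.1e-14 for the G1/S list (adjusted p = 0.023 with an estimated correlation).

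In the amino acid and ATF4 response list, 10 of 17 genes rose and 0 fell by limma (13 rose adjusted over the list alone), with a median log2 fold change of 0.26. SLC7A11, the cystine transporter, rose from 4.65 ± 0.0521 to 8.43 ± 0.810 RPKM, asparagine synthetase ASNS from 12.04 ± 0.793 to 16.6 ± 0.395 RPKM, and the stress-induced transcription factor ATF3 from 2.63 ± 0.0553 to 3.81 ± 0.196 RPKM. ATF4 itself, chosen after its values were seen, measured 121 ± 2.10 and 125 ± 1.58 RPKM (adjusted p = 0.273). In the list of the NRF2 oxidative stress response 9 of 16 genes rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.22. The aldo-keto reductase AKR1C2 rose from 117 ± 1.10 to 192 ± 3.89 RPKM, AKR1C1 from 19.9 ± 0.705 to 31.7 ± 0.915 RPKM, and GCLC, of glutathione synthesis, from 12.3 ± 0.345 to 17.8 ± 0.444 RPKM. The gene of this list that fell was TXNRD1, thioredoxin reductase, from 130.0 ± 3.09 to 99.6 ± 2.16 RPKM, named after its values were seen. Camera gave an adjusted p of 8.7e-06 for the ATF4 list (adjusted p = 0.056 with an estimated correlation) and 8.4e-05 for the NRF2 list (adjusted p = 0.237 with an estimated correlation). SLC7A11 belongs to both lists.

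The remaining 23 lists tested by camera did not pass. By fry, which tests each list by itself, some of them did: Wnt targets (adjusted p = 0.0055), MYC targets (0.015) and heat shock (0.016). Fatty acid and triglyceride synthesis (0.018), autophagy and lysosome (0.021) and the TGF-beta list (0.038) passed by fry as well. The smallest adjusted p by camera among the 23 was 0.1004, for MYC targets and ribosome biogenesis. In that list 5 of 18 genes rose and 1 fell (5 and 1 adjusted over the list alone; 5 to 6 rose and 0 to 1 fell with 1 library left out), among them MYC from 7.53 ± 0.485 to 10.7 ± 0.677 RPKM and the nucleolar protein NOLC1 from 106 ± 1.90 to 179 ± 3.35 RPKM. This list passed without mimics-NC replicate 2 (adjusted p = 0.0401) and without mimic replicate 1 (adjusted p = 0.0118), both with the preset correlation, while with all 6 libraries an estimated one gave an adjusted p of 0.703. None of the 26 ribosomal proteins passed by limma (0 adjusted over the list alone), 2 had an unadjusted p under 0.05 and 2 passed by voom. Their median was 0.0040, their mean -0.0092 and the direction by camera down, and RPL5, the most abundant, measured 876 ± 57.7 and 792 ± 49.96 RPKM.

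In cholesterol synthesis 6 of 22 genes rose and 2 fell (6 and 2 adjusted over the list alone). The count was 2 to 3 higher and 2 lower with 1 library left out, and 3 higher and 2 lower under median-of-ratios scaling. The synthase HMGCS1 rose from 59.9 ± 2.21 to 73.2 ± 0.416 RPKM and INSIG1, which holds back sterol synthesis, fell from 8.08 ± 0.435 to 5.82 ± 0.343 RPKM. In fatty acid and triglyceride synthesis 2 of 16 rose and 2 fell (2 and 2 adjusted over the list alone; 1 to 2 fell with 1 library left out). Malic enzyme ME1 rose from 15.4 ± 0.807 to 24.4 ± 0.0906 RPKM and AGPAT2 fell from 4.21 ± 0.426 to 2.80 ± 0.2503 RPKM. In fatty acid oxidation 3 of 15 rose and 0 fell by limma (5 and 0 adjusted over the list alone; 0 to 5 rose with 1 library left out). ETFB rose from 10.3 ± 0.598 to 12.2 ± 0.345 RPKM, a call lost without mimics-NC replicate 2 or mimic replicate 2 (adjusted p up to 0.0579). Of the other genes of this list that rose, HADHB kept its call only without mimics-NC replicate 1 (adjusted p up to 0.0949) and ETFDH only without mimics-NC replicate 3 or mimic replicate 1 (up to 0.0771). In glycolysis 1 of 19 rose and 3 fell (1 and 3 adjusted over the list alone; 1 to 3 fell with 1 library left out). PFKM measured 22.5 ± 0.730 and 28.1 ± 0.687 RPKM and LDHA, lactate dehydrogenase, 75.0 ± 1.52 and 63.2 ± 1.01 RPKM. Of the other genes of this list that fell, HK1 kept its call only without mimic replicate 2 (adjusted p up to 0.129) and TPI1 only without mimics-NC replicate 3 or mimic replicate 2 (up to 0.0826). Of 26 nuclear genes of oxidative phosphorylation 1 rose and 0 fell by limma (1 and 0 adjusted over the list alone; 1 to 2 rose with 1 library left out). None of the 13 mitochondrially encoded genes passed by limma (0 adjusted over the list alone), 1 had an unadjusted p under 0.05 and 2 passed by voom. Without mimic replicate 1 this list gave a camera adjusted p of 0.00587 with the preset correlation, with the direction down and 4 genes lower, while with all 6 libraries the estimated correlation was 0.807 and gave an adjusted p of 0.902.

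Of 18 hepatocyte secreted proteins 1 rose and 0 fell by limma (0 and 0 adjusted over the list alone): ITIH2, from 58.7 ± 1.17 to 64.4 ± 1.75 RPKM, a call lost with any 1 library left out (adjusted p 0.0594 to 0.112). FGB, the fibrinogen beta chain, measured 2106 ± 20.4 and 1947 ± 48.6 RPKM and albumin (ALB) 52.4 ± 2.26 and 52.3 ± 1.73 RPKM. AFP, alpha-fetoprotein, which Huh7 cells are known to secrete, measured 1.24 ± 0.0512 and 1.18 ± 0.168 RPKM, and TTR, transthyretin, 0.271 ± 0.0668 and 0.584 ± 0.194 RPKM. ALB, AFP and TTR were chosen after their values were seen. Of 14 hepatocyte transcription factors 2 rose and 2 fell (2 and 3 adjusted over the list alone; 0 to 1 rose and 0 to 1 fell with 1 library left out). HNF4G measured 1.52 ± 0.0406 and 1.14 ± 0.0332 RPKM, a call lost without mimics-NC replicate 2 or 3 or mimic replicate 2 (adjusted p up to 0.0663). In drug and bile acid metabolism 2 of 4 rose and 0 fell by limma (3 and 0 adjusted over the list alone), too few for camera: UGT1A1, which conjugates bilirubin, from 25.1 ± 0.663 to 41.5 ± 1.33 RPKM, and the export pump ABCC2 from 69.1 ± 2.49 to 85.5 ± 0.700 RPKM. UGT1A1 overlaps other UGT1A genes on the same strand, such as UGT1A6, and how reads were assigned among them was not tested. Of 7 acute phase genes FGL1 rose from 16.7 ± 0.857 to 20.7 ± 0.651 RPKM and 0 fell by limma (1 and 0 adjusted over the list alone), while the list's median was -0.036, its mean 0.035 and its direction by camera up.

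In the stress lists, heat shock had 0 of 13 genes higher and 2 lower by limma (1 and 2 adjusted over the list alone): the co-chaperone BAG3 fell from 29.6 ± 1.49 to 18.3 ± 0.495 RPKM and HSPH1 from 45.7 ± 1.39 to 33.0 ± 1.07 RPKM. In hypoxia 1 of 12 rose and 5 fell (3 and 6 adjusted over the list alone; 1 to 2 rose and 2 to 3 fell with 1 library left out). NDRG1 measured 8.07 ± 0.204 and 6.30 ± 0.286 RPKM and VEGFA, a growth factor for vessels, 14.8 ± 0.243 and 17.4 ± 0.378 RPKM. In the unfolded protein response 2 of 18 rose and 1 fell (4 and 4 adjusted over the list alone), with HERPUD1 rising from 4.02 ± 0.246 to 5.17 ± 0.211 RPKM. The gene of this list that fell, PDIA4, lost its call with any 1 library left out (adjusted p 0.0525 to 0.143), while 4 fell under median-of-ratios scaling and 4 under quantile normalization. Among p53 targets 2 of 15 rose and 2 fell (2 and 2 adjusted over the list alone; 1 to 2 rose with 1 library left out). SESN2 rose from 3.96 ± 0.175 to 5.37 ± 0.218 RPKM and MDM2, which degrades p53, fell from 8.60 ± 0.290 to 6.96 ± 0.124 RPKM. Of 15 apoptosis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; 2 to 4 rose with 1 library left out). The caspase CASP8 rose from 15.6 ± 0.185 to 18.997 ± 0.179 RPKM and PMAIP1 fell from 12.9 ± 0.911 to 8.52 ± 0.234 RPKM. Of 21 autophagy and lysosome genes 3 rose and 0 fell by limma (3 and 0 adjusted over the list alone; 2 to 3 rose with 1 library left out), with WIPI1 rising from 8.69 ± 0.0759 to 12.1 ± 0.335 RPKM. Of the metallothioneins 1 was tested, MT2A, at 2.03 ± 0.0764 and 1.83 ± 0.490 RPKM (adjusted p = 0.539). Of 3 histone genes tested HIST1H2AC rose and 0 fell by limma (2 and 0 adjusted over the list alone), at 1.04 ± 0.0677 and 1.48 ± 0.142 RPKM, a call kept only without mimics-NC replicate 3 or mimic replicate 1 (adjusted p up to 0.0778).

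In the signalling lists, NF-kB and inflammation had 2 of 13 genes higher, CXCL1 and CXCL8 (22.4 ± 1.65 to 28.2 ± 0.620 RPKM), and NFKBIE lower, from 8.80 ± 0.764 to 6.12 ± 0.557 RPKM (2 and 1 adjusted over the list alone). Its median was -0.065, its mean 0.031, and its direction down by camera and up by fry. In the interferon and double-stranded RNA response 1 of 12 rose and 1 fell (1 and 1 adjusted over the list alone): OAS1, at 1.74 ± 0.105 and 2.29 ± 0.168 RPKM, kept its call only without mimics-NC replicate 3 or mimic replicate 1 (adjusted p up to 0.0681), and IFIT3, at 1.57 ± 0.194 and 1.12 ± 0.0631 RPKM, only without mimics-NC replicate 3 (adjusted p up to 0.105). Of 6 Wnt targets MYC and TBX3 rose and 0 fell by limma (2 and 0 adjusted over the list alone). In TGF-beta and epithelial-mesenchymal transition 4 of 11 rose and 1 fell (5 and 2 adjusted over the list alone; 2 to 3 rose and 0 to 1 fell with 1 library left out). CYR61, a secreted matrix protein, rose from 4.0004 ± 0.138 to 5.82 ± 0.266 RPKM and TGFBR2, a TGF-beta receptor, from 9.73 ± 0.393 to 12.8 ± 0.252 RPKM. The gene of this list that fell, TGFB1, kept its call only without mimics-NC replicate 2 (adjusted p up to 0.137), and ITGA5, which rose, only without mimics-NC replicate 1 (up to 0.113). Of 11 MAPK feedback genes 1 rose, DUSP4, and 0 fell by limma (0 and 0 adjusted over the list alone), from 3.21 ± 0.0861 to 3.74 ± 0.139 RPKM, a call kept only without mimic replicate 1 (adjusted p up to 0.101). CCND1 measured 38.6 ± 1.30 and 39.2 ± 0.728 RPKM.

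Markers of other cell types gave no group to test. Of the immune markers CD68 (36.7 ± 1.38 and 36.1 ± 1.605 RPKM) and LYZ (9.56 ± 0.885 and 10.99 ± 1.52 RPKM) were tested, and of the endothelial markers PECAM1 (4.21 ± 0.0248 and 4.37 ± 0.197 RPKM). None of these 3 passed by limma (0 adjusted over the list alone), 0 had an unadjusted p under 0.05 and 0 passed by voom. No fibroblast or stellate marker and no cholangiocyte marker reached a mean of 1 RPKM, the highest being COL1A2 at 0.892 and SOX9 at 0.874 RPKM.

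**Figure D2:**
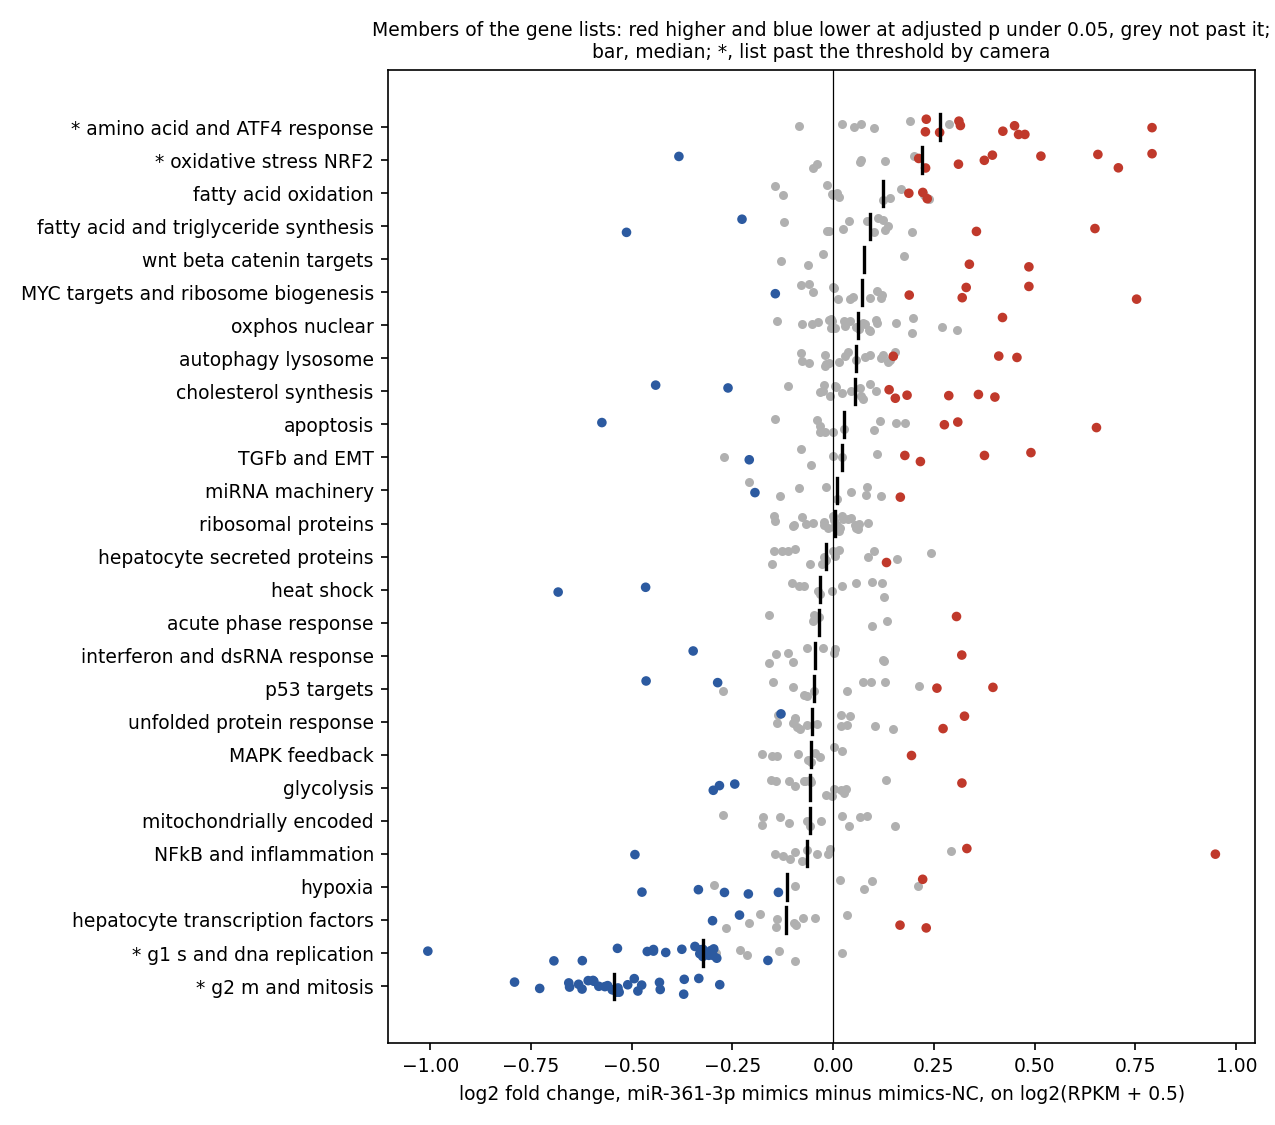
Log2 fold change (horizontal axis, mimic minus mimics-NC) of the members of the 27 lists tested, 1 line of points per list, with a bar at each list's median and an asterisk at the 4 lists past the camera threshold; red genes rose, blue genes fell and grey genes did not pass. The medians of the G2/M list (-0.54) and the G1/S list (-0.32) lie to the left of 0, and those of the ATF4 list (0.26) and the NRF2 list (0.22) to the right.

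The next comparison asked whether transcripts with a miR-361-3p site in the 3' UTR were lower with the mimic, as base pairing of a microRNA's seed with a 3' UTR is known to lower a transcript. The 2575 genes with a site had a median log2 fold change of 0.0067 and the 7272 genes without one a median of 0.011, a difference of -0.0041, for which camera gave a p of 0.893. Of the genes with a site 10.3% fell and 11.4% rose, against 11.5% and 13.02% of those without. In a linear model with 3' UTR length, GC content and expression, the site's coefficient was -0.00052 (SE 0.0049, 95% interval -0.010 to 0.0090). This SE and interval treat genes as independent and leave out the spread between libraries. Set against the mimics-NC mean, the uncorrected difference was 0.00082, -0.013 and 0.00097 in mimic replicates 1, 2 and 3 (SD 0.0080). For the 577 genes with an 8mer site the difference was 0.00040 and camera gave a p of 0.989. The sites are those of mature miR-361-3p, and whether the mimic has its sequence was not checked. The same difference for CTGGGGG ranked 9 from the lowest among the 42 7-mers of the same bases. Genes with sites of miR-361-5p, miR-122-5p and miR-1-3p gave camera p of 0.660, 0.959 and 0.869.

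Individual genes with an 8mer site did fall. MKI67 holds the site at bases 1902 to 1909 of its 3' UTR, RPS6KA4, a kinase of the MAPK pathway (chromosome 11, 64359148 to 64372215), at 481 to 488, and DTX4, an E3 ligase (chromosome 11, 59171430 to 59208587), at 3033 to 3040. RPS6KA4 fell from 3.29 ± 0.451 to 1.81 ± 0.0809 RPKM, DTX4 from 4.88 ± 0.270 to 3.08 ± 0.188 RPKM, and EFCAB14 from 9.03 ± 0.222 to 5.96 ± 0.168 RPKM. SAPCD2, IQCC, TP53INP1 and BCL2L2, which protects from apoptosis, had log2 fold changes of -0.68, -0.48, -0.46 and -0.46. Of the 577 genes with an 8mer site 52 fell and 57 rose, 9.01% and 9.88%, against 11.3% and 12.8% of the other genes.

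**Figure D3:**
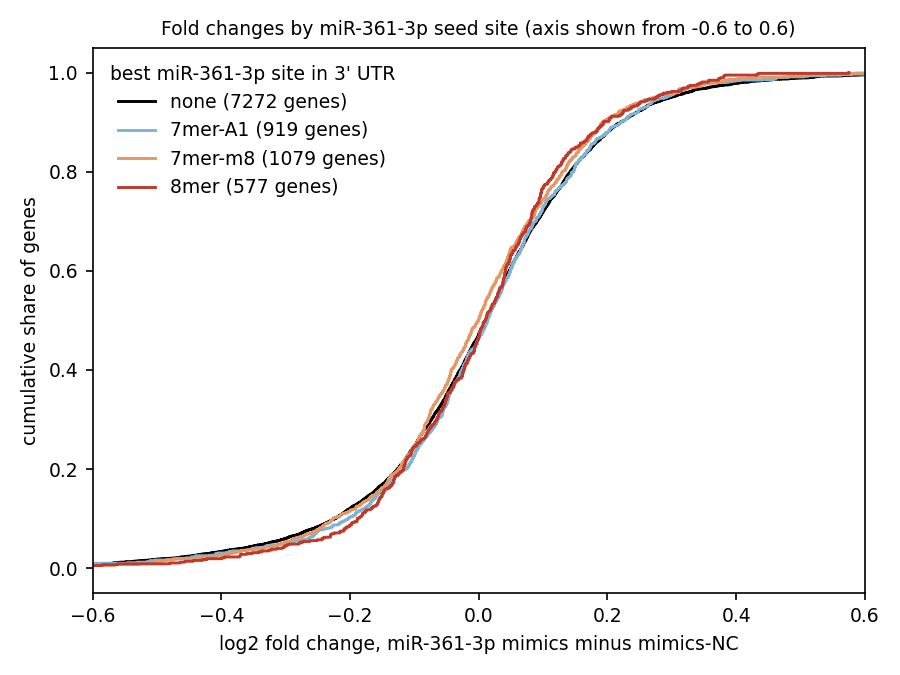
Cumulative share of genes (vertical axis) by log2 fold change (horizontal axis, mimic minus mimics-NC) for genes with no miR-361-3p site (7272), a 7mer-A1 site (919), a 7mer-m8 site (1079) or an 8mer site (577) in the 3' UTR. The 4 curves run close together, with a median difference of -0.0041 between genes with any site and genes without.

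The last comparison covered the microRNA's host gene and the proteins that process and load microRNAs. CHM, whose intron holds miR-361 (chromosome X, 85861180 to 86047562), rose from 3.19 ± 0.117 to 3.85 ± 0.131 RPKM, a log2 fold change of 0.24 (adjusted p = 0.0178). Its call was lost without mimics-NC replicate 1 (adjusted p = 0.0506) or 2 (0.0613) and without mimic replicate 1 (0.0562) or 3 (0.0587). Of 11 microRNA machinery genes 1 rose and 1 fell (1 and 2 adjusted over the list alone). AGO1, an Argonaute protein that holds the loaded strand, measured 7.85 ± 0.127 and 8.88 ± 0.391 RPKM, and its call was kept only without mimic replicate 2 (adjusted p up to 0.116). DGCR8, the partner of DROSHA, measured 9.47 ± 0.0935 and 8.23 ± 0.501 RPKM, and its call was kept only without mimic replicate 1 (adjusted p up to 0.0966). DROSHA measured 11.8 ± 0.332 and 12.9 ± 0.480 RPKM and DICER1 10.6 ± 0.344 and 10.99 ± 0.731 RPKM, both chosen after their values were seen. The median of this list was 0.0089, its mean -0.012 and its direction by camera down (adjusted p = 0.841). The mimic itself is too short to be read in these libraries.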

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

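The voom fit, the scaling without mitochondrially encoded genes and the principal transcripts were chosen after seeing the data, and all other alternatives before. The count of 2835 genes stayed within 1.5 times under other pseudocounts, minimums of 0.5 and 5 RPKM, other scalings, other limma options, protein-coding genes alone (3148) and voom (3821), though under median-of-ratios scaling 1356 rose and 1453 fell. It was 1716 (870 rose, 846 fell) with no filter, where 33707 genes share the adjustment, 1160 (534 and 626) at an adjusted p under 0.01, and 7 (2 and 5) with an absolute log2 fold change of at least 1, all stricter by construction. With 1 library fewer it was 1780 to 2150 genes, 895 to 1193 of which rose, with fewer samples in each fit. With the replicate number as a block 1976 genes passed, but residuals of same-numbered libraries correlated at -0.052, -0.016 and 0.023 across genes, so the numbers do not pair the libraries, and a call lost under the replicate block is not a weaker effect. Of the 106 named genes past the threshold none changed sign in any setting, and 31 lost the call with some library left out. The groups lay apart for every called gene, so leaving out a library or changing the pseudocount could not change a sign. CHM gave log2 fold changes of 0.22 to 0.26 with 1 library fewer. Of the lists 1 passed with an estimated correlation and 10 by fry, which asks another question, and 5 by voom. Counts of genes within small lists moved with the setting: under median-of-ratios scaling 0 secreted proteins and 0 machinery genes rose and 2 NF-kB genes fell, and by voom 8 genes of fatty acid oxidation, 6 nuclear genes of oxidative phosphorylation, 7 autophagy genes and 5 of fatty acid synthesis rose. The 4 called lists passed under all 14 other settings with the preset correlation, with adjusted p up to 0.00045. In 24 cases over 13 results a direction was counted as reversed, none of them past the threshold, and the cause was not tested. With at least 5 RPKM the microRNA machinery, secreted proteins and p53 targets reversed (adjusted p = 0.962 each), as did NF-kB by fry (0.195), the 8mer difference (0.00040) and RPL19 under median-of-ratios scaling (-0.0049). MT-CO3 under quantile normalization was counted too, but its value was 0, which is no opposite direction. With 1 library fewer, ranges that include a reversal were adjusted p of 0.610 to 0.986 for machinery, 0.621 to 0.914 for secreted proteins, 0.00587 to 0.874 for mitochondrially encoded genes, 0.724 to 0.927 for p53 targets and 0.368 to 0.933 for ribosomal proteins, and log2 values of -0.0078 to 0.0012 for the site difference, -0.0048 to 0.042 for CCND1, -0.057 to 0.0037 for CD68, -0.040 to 0.14 for MT-ATP6, -0.017 to 0.15 for MT-CO3, -0.29 to 0.017 for MT2A and -0.032 to 0.056 for RPL19. The lowest correlation within a group was 0.9898 and 0.9942 with pseudocounts of 0.1 and 1, and 0.9916 and 0.9957 with minimums of 0.5 and 5 RPKM. Read-based tests by edgeR and DESeq2 were planned if reads could be recovered and were not run, voom standing in for them, and the longest 3' UTR was already in use.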

Other observations

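The tests of 3' UTR length and GC content, of sites followed by A, of the control duplex and of coding sequences by scan, and the count of lists over other splits, were chosen only after the results they measure had been seen. The test of 3' UTR length and GC content replaced earlier forms, whose motifs came from a scan already corrected for both. The 7-mer scan, first run with fewer genes matched to GENCODE, the shuffles, the test of motifs in coding sequence only and the list of YAP and TEAD targets were chosen after the changes of single genes had been seen, while the count of genes over other splits was planned.

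Target genes of YAP and TEAD, regulators of transcription in cell spreading and growth, rose more often than they fell. Of 14 tested besides ANKRD1, 6 rose, CYR61 (0.49), MYOF (0.53), F3 (0.42), DOCK5 (0.33), IGFBP3 (0.26) and CRIM1 (0.24 on the log2 scale), NT5E fell (-0.24) and CTGF had a value of -0.0013. The list gave a camera p of 0.0074 with the preset correlation and 0.079 with an estimated one, which is consistent with a rise of the group beside EREG, ANKRD1 and TPM4, a hypothesis from the same data. CYR61 and CTGF are also members of the TGF-beta list.

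Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 2835 genes, and the highest of the others gave 0 by limma, with 249 to 482 genes at an unadjusted p under 0.05. For lists, 7 of the 10 splits gave at least 4, the real value, and the highest of the others gave 7. With 10 splits no share under 0.1 can be had. Each other split still sets 2 libraries of one transfection against 1.

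A scan of 16283 7-mers in the 3' UTRs of 9847 genes, corrected for 3' UTR length, GC content and expression, asked which sequences went with lower transcripts. CAGAAGT ranked 1, with a corrected log2 difference of -0.058 between the 1621 genes with it and those without (z = -10.2). GCAGAAC ranked 3 (925 genes, -0.058, z = -8.33), while miR-361-3p's CTGGGGG ranked 4383 (z = -0.654). These z, and the SE and shuffles below, treat genes as independent and leave out the spread between libraries. Of the 84 genes that fell at least 1.5-fold and have a 3' UTR, 38 (45.2%) hold CAGAAGT or GCAGAAC, against 23.2% of all. The motifs were picked on these same fold changes, so this excess is no separate support. Neither share is corrected for 3' UTR length. SOAT1 holds 3 of these motifs, SH3GL1 2, and CCNE1, NUF2, PHF8 and NELFCD 1 each, while MYBL2, ZMYND19, ABCB10 and UBE2M hold 0 and ANKRD1, which rose, holds 1.

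The shuffles argue against the number of 7-mers scanned as the source of the lower CAGAAGT and GCAGAAC genes: 0 of 100 reached the z of GCAGAAC (lowest -4.98). A scan with no correction in 4923 genes drawn at random ranked the motifs 1 and 4 from the lowest. In the remaining 4924 genes the corrected change was -0.044 per motif (SE 0.0047), against -0.033 (SE 0.0041) uncorrected. The correction thus did not shrink the change. The 2 motifs had, however, first been chosen from a scan of all genes, these included, already corrected for 3' UTR length and GC content. A corrected change below 0 was therefore likely from the start. It does not decide whether 3' UTR length and GC content are the source. Of the 10 7-mers picked with no correction, 9 kept a corrected z under -2. These 9 are the 2 motifs and 7-mers that overlap them, so they are not separate signals. CGATACC, the pick that does not overlap them, had a corrected z of 0.822. Genes with a motif in the coding sequence only also had lower values (2348 genes, -0.041, SE 0.0048, against -0.078, SE 0.0053, with a motif in the 3' UTR; the contrast with 0.5 of the latter was -0.0019, SE 0.0047), which leaves open a property of the genes rather than of the 3' UTR, though pairing in coding sequence would give the same. Sites followed by A went with a larger fall than those without, by -0.052 (SE 0.011) for CAGAAGT and -0.073 (SE 0.013) for GCAGAAC. Separate short RNAs with the seeds ACUUCUG and GUUCUGC in the mimic libraries would give this. The corrected scan of all genes had, however, already ranked AGAAGTA 2 and CAGAACA 5 from the lowest. These are the ends of the same sites with the A included. The larger fall was thus already in view in the same fold changes, so it does not decide whether such RNAs were present. Neither seed is that of a strand of miR-361, the sequence of the mimic was not checked, and no such RNA was identified. A scan of coding sequences ranked GCAGAAC 1 and CAGAAGT 2 of 16381 7-mers.

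Genes with TCGGAGA in the 3' UTR were higher with the mimic (193 genes, 0.086, z = 6.06, rank 2), and 0 of 100 shuffles reached this z (highest 4.71), which argues against the number of 7-mers scanned. TCGGAGA is the site of UUCUCCGAACGUGUCACGU, a control sequence recalled from memory and given in none of the sources used here, so a candidate explanation, if the mimics-NC had this seed, is that the control lowered these genes in the mimics-NC libraries. A scan of coding sequences ranked TCGGAGA 1 from the highest (726 genes, 0.045, z = 5.95), which likewise leaves open a property of the genes. The 55 genes with TCGGAGA followed by A gave 0.15 (SE 0.026). The site of the duplex's other strand gave 0.014 (SE 0.012, 294 genes), which does not decide, and another control, also recalled from memory for the supplier in the labels, was not tested.

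AFP and TTR, at 1.21 and 0.428 RPKM over the 6 libraries, lay far under FGB at 2026 RPKM, and the identity of the line was not tested.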
